A study of Mus musculus with 4 samples.

How the data were processed

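ATAC-seq was performed on 4 libraries of mouse J1 embryonic stem cells, 2 of the MERVL-positive, Zscan4c-positive population (DR+/+) and 2 of the population negative for both (DR-/-). Per the labels' protocols, cells were grown on gelatin in medium with 15% serum and 1000 units/mL leukemia inhibitory factor, nuclei were incubated with Tn5 at 37 °C for 30 min, and paired reads of 50 bp were sequenced. Libraries were grouped by their titles, and the replicate numbers are those of the titles.

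Per the submitters' processing notes, FastQC 0.10.1, Bowtie2 2.3.0 and SAMtools 0.1.19 were used with the mm9 build, without stated roles. The peak caller, its settings, any shift of reads to the Tn5 insertion site, and the treatment of duplicate, mitochondrial and multiply mapped reads are not given in the sources used here. Multiply mapped reads matter for repeats such as MERVL, since their handling decides whether peaks in repeat copies can be called. The deposited files are peak lists in narrowPeak layout, 1 per library, so replicates were not pooled. Positions on chromosome 1 reached 197108341, beyond the last gene (195291439) of the GRCm38 table, and names such as Y_random occur, both of which go with mm9. The gene table supplied is of GRCm38, so it was not joined to the peaks. The planned comparisons by promoter, gene list and sequence content were therefore not made.

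The values the authors deposited per peak are a score (the whole-number part of 10 times the −log10 q-value, in 99.95% or more of the peaks of each list), a fold enrichment (ratio) over local background, a −log10 p-value and a −log10 q-value. The smallest −log10 q-value was 1.31 to 1.32 in every list, a q-value of 0.05. All of these deposited values belong to 1 library and were used to rank, filter and describe peaks within it. The deposited summit position was not used.

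All computations were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures with Matplotlib 3.10.9. Peaks of the 4 lists that overlapped by at least 1 bp were merged into 50231 union regions. A region was present in a library if any of its peaks overlapped it. Regions present in both libraries of a population and in neither of the other are called specific to that population, and regions present in all 4 libraries are called common. Shares carry 95% Wilson intervals, ratios of counts a normal interval on the log scale, and both cover counting error only. Overlap by chance was measured with 100 random circular shifts per pair of lists. Chromosomes were compared with two-sided and 1 Mb windows with one-sided Fisher's exact tests, each adjusted by Benjamini-Hochberg at 0.05 within its family and population. Widths and distances were compared with permutation tests of 100000 resamples, with regions and not libraries as the units. Library-level means were compared with exact permutation tests.

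The read depth is not stated in the lists. Fold enrichment was taken as (pileup + 1)/(background + 1) and the p-value as a Poisson upper tail. Under this form 100% of the peaks in each list gave a whole-number pileup whose −log10 p-value lay within 0.001 of the deposited one. The lowest background of a list, shared by 906 to 2847 of its peaks, was taken as proportional to sequencing depth times the length to which reads were extended. That length is not known, and the shortest peak of each list was used in its place as an alternative.

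The regions named in the text are those with the highest mean percentile of their 2 q-values within the lists, 15 for DR+/+ and 10 for DR-/-, and the windows with the smallest p. The report gives the first 4 for DR+/+ and the first 3 for DR-/-, and of the others some picked after their values were seen, for their chromosome or width. This rule, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. The alternatives were the top 50% of each list, lists of equal length, 50% reciprocal overlap, 1 kb bins, merging over gaps of 500 bp, windows of 500 kb or with at least 5 regions, autosomes alone, each library left out, and a replicate block. Presence in the stronger 50% of the list, common regions as background, and the replicate 2 libraries alone were added after seeing the data. The recovery by quartile, the background pileup and the direct comparison of the populations by chromosome were also chosen after the data were seen. The interval and window code was tested on simulated data. With labels drawn at random over the 50231 regions, 0 windows and 0.1 chromosomes were called per run, and a planted 1.5-fold excess on the X chromosome was recovered in 100% of runs and a 1.25-fold one in 70%. No pair of lists was identical, the highest Jaccard index being 0.443, so all 4 libraries were kept as separate samples.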

Results

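Chromatin accessibility was compared between 2 populations of J1 mouse embryonic stem cells, a line of 129SV strain origin grown without feeders in serum and leukemia inhibitory factor. The populations were defined by MERVL and Zscan4c. MERVL is an endogenous retrovirus whose long terminal repeats are active in the early embryo, and Zscan4c belongs to a gene family expressed at zygotic genome activation. The comparison asked which sites are accessible in cells positive for MERVL and Zscan4c, a state likened to the 2-cell embryo. Cells positive for both formed the DR+/+ population and cells negative for both the DR-/- population, with 2 libraries each. The assay was ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into accessible DNA. Each library is represented by its own list of peaks on the mm9 genome. The labels do not say whether the 2 libraries of a population came from separate cultures, so the spread between them may be technical.

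More accessible sites were called in the DR+/+ libraries than in the DR-/- libraries. The lists held 40933 and 26866 peaks in DR+/+ replicates 1 and 2, and 21630 and 24432 peaks in DR-/- replicates 1 and 2. The group means were 33899.5 ± 9946.87 peaks for DR+/+ and 23031 ± 1981.31 for DR-/- (SD, n = 2 each). The peaks covered 7.85 ± 2.39 Mb in DR+/+ and 4.74 ± 0.478 Mb in DR-/- (SD, n = 2 each). Peaks were also wider in both DR+/+ lists, with median widths of 188 and 189 bp against 173 and 176 bp. Their shortest peaks were longer as well, at 108 and 115 bp against 104 and 103 bp. An exact two-sided permutation test of 2 against 2 libraries gave p = 0.33 for the number of peaks, which is the smallest p this test can give with 2 against 2 libraries, so no library-level difference can pass 0.05 in it. The difference of 10868.5 peaks fell to 3835 without DR+/+ replicate 1 and was 17902 without DR+/+ replicate 2.

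The read totals of the libraries are not given in the peak lists, but the fold enrichment and p-value of every peak together returned a whole number of reads piled up at its summit. The same calculation returned the lowest background pileup in each list, which was 1.66 and 1.62 in DR+/+ replicates 1 and 2 and 1.31 and 1.47 in DR-/- replicates 1 and 2. Per unit of this background, DR+/+ replicate 1 had 24606 peaks, whereas DR+/+ replicate 2 and DR-/- replicates 1 and 2 had 16582, 16533 and 16580. Divided further by the shortest peak of each list, 108, 115, 104 and 103 bp in the order DR+/+ replicates 1 and 2 and DR-/- replicates 1 and 2, the background per 100 bp was 1.54, 1.41, 1.26 and 1.43. The median summit pileup was 16 reads in both DR+/+ libraries and in DR-/- replicate 2 and 15 reads in DR-/- replicate 1, so a typical peak rested on few reads.

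**Figure D1:**
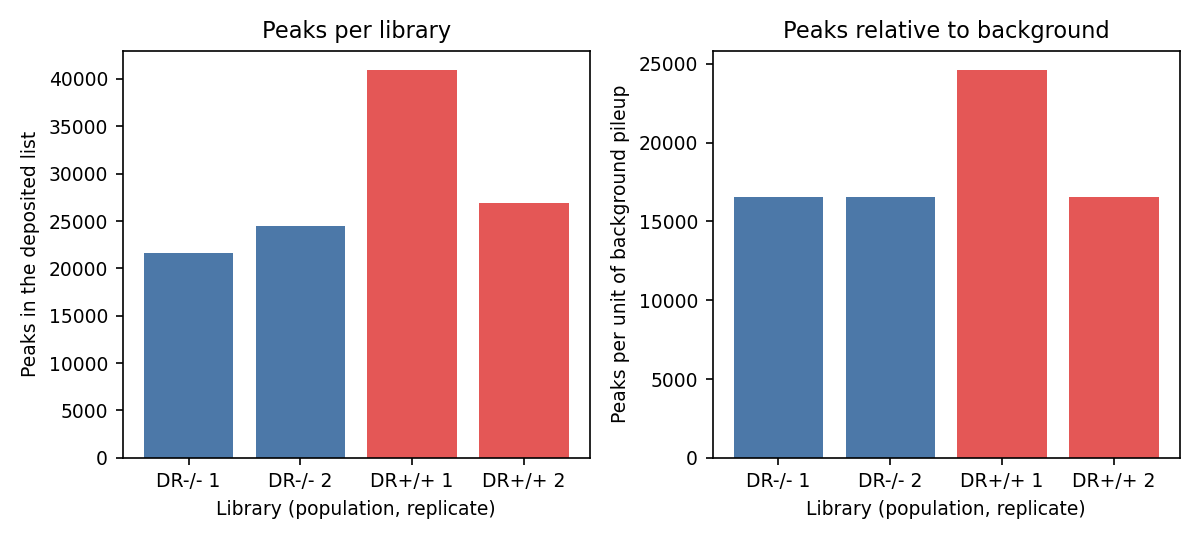
Number of peaks in each deposited list (left, y axis in peaks) and the same number divided by the lowest background pileup of the list (right, peaks per unit of background pileup). Each bar is 1 library, DR-/- in blue and DR+/+ in red. DR+/+ replicate 1 stands above the other 3 libraries in both panels, with 24606 peaks per unit of background.

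Most strong sites were shared between the populations, and the lists diverged among the weaker ones. Of the strongest quartile of the peaks of DR-/- replicate 1, 97.2% were overlapped by a peak of DR-/- replicate 2, and 98.3% and 95.4% by a peak of DR+/+ replicates 1 and 2. The strongest quartile of DR+/+ replicate 1 was overlapped less, at 85.2% and 88.5% in DR-/- replicates 1 and 2 and 92.6% in DR+/+ replicate 2. In this longer list the quartile held 10232 peaks, against 5405 for DR-/- replicate 1, and so reached further down the ranks. The strongest quartile of DR+/+ replicate 2, with 6717 peaks, was overlapped at 89.8% and 92.3% in DR-/- replicates 1 and 2 and 98.7% in DR+/+ replicate 1. Of the weakest quartile of DR-/- replicate 1, 46.5% were found in DR-/- replicate 2, 66.5% in DR+/+ replicate 1 and 47.0% in DR+/+ replicate 2. Over the whole list of DR-/- replicate 1 the shares were 72.3% in DR-/- replicate 2, 83.2% in DR+/+ replicate 1 and 70.5% in DR+/+ replicate 2. The longest list, that of DR+/+ replicate 1, overlapped 81.5% of the peaks of DR-/- replicate 2 as well. Of the peaks of DR+/+ replicate 2, 82.3% were overlapped in DR+/+ replicate 1, and 55.5% and 60.1% in DR-/- replicates 1 and 2. Random shifts of the shorter list along its chromosomes gave mean overlaps of at most 0.464% over the 6 pairs.

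Measured by shared bases, libraries of 1 population resembled each other more than libraries of different populations. The Jaccard index, the shared length divided by the joint length, was 0.443 between the DR-/- libraries and 0.420 between the DR+/+ libraries. Between populations it ranged from 0.33 (DR-/- replicate 1 with DR+/+ replicate 1) to 0.399 (DR-/- replicate 2 with DR+/+ replicate 2). The mean within populations exceeded the mean between them by 0.0622, whereas the other 2 splits of the 4 libraries into pairs gave -0.0360 and -0.0262. With 3 possible splits this ranking cannot pass 0.05. Leaving out DR-/- replicate 1 lowered the difference to 0.0380. Lists that cover unequal lengths cannot overlap fully, which lowers the index. With each list limited to its 21630 strongest peaks the difference was 0.0507.

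**Figure D2:**
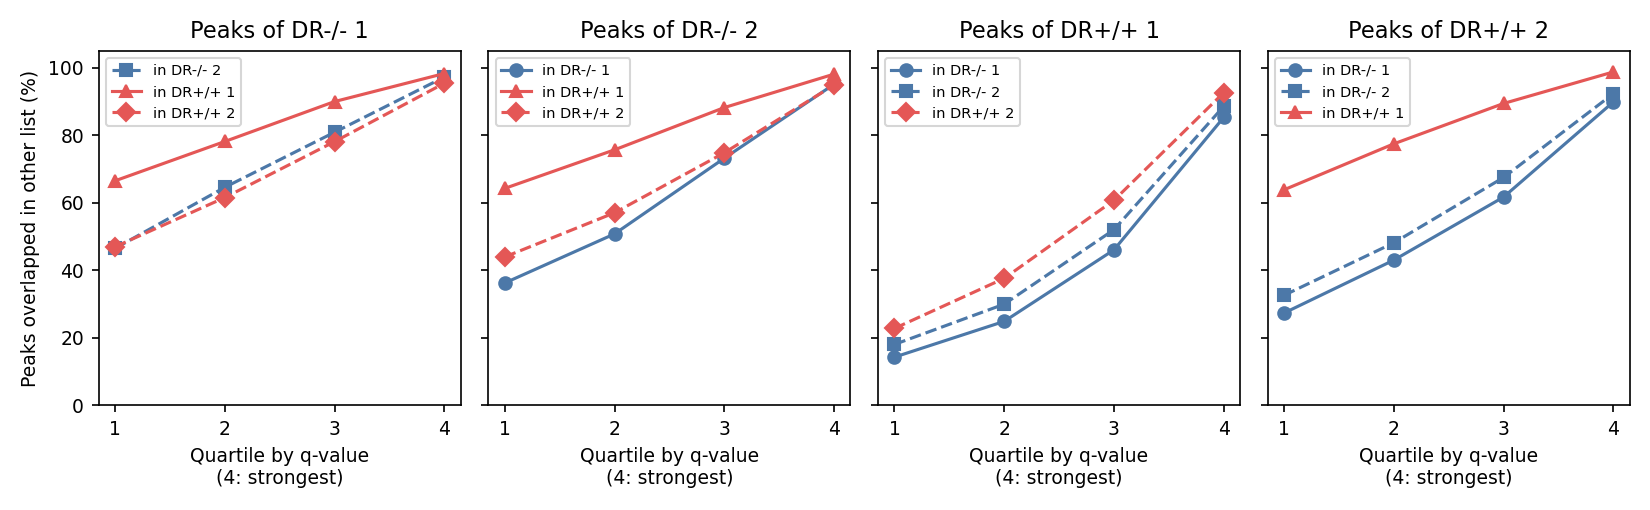
Share of the peaks of each library (panels) that were overlapped by at least 1 bp in each other library, y axis in percent, by quartile of the library's own q-values on the x axis (4 is the strongest). Lines to DR-/- lists are blue and lines to DR+/+ lists red. In the strongest quartile of DR-/- replicate 1 the shares lie between 95.4% and 98.3%, and in the weakest between 46.5% and 66.5%.

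The main comparison asked which sites were called accessible in 1 population alone. Merging overlapping peaks of the 4 libraries gave 50231 union regions, of which 12412 (24.7%, 95% Wilson interval 24.3 to 25.1%) were called in all 4 libraries. A further 4560 regions (9.08%, 8.83 to 9.33%) were called in both DR+/+ libraries and in neither DR-/- library. Only 691 regions (1.38%, 1.28 to 1.48%) were called in both DR-/- libraries and in neither DR+/+ library. The former, termed DR+/+-specific regions, outnumbered the latter 6.60-fold (95% counting interval 6.09 to 7.15). Regions shared by a pair of libraries from different populations, and by no other library, numbered 305 to 2151. Of the 3 ways to split the libraries into pairs, the split by population gave 5251 pair-specific regions, against 1827 and 2456 for the others. These intervals cover counting error only, and presence calls on 2 against 2 libraries allow no test per region.

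The excess of DR+/+-specific regions depended on the lengths of the lists. When each list was limited to its 21630 strongest peaks, the length of the shortest list, 1791 regions were DR+/+-specific and 1516 DR-/--specific, a ratio of 1.18 (counting interval 1.1 to 1.27). Equal lengths bring the 2 counts closer by construction. Each library moved the counts. Without DR+/+ replicate 1, 8652 and 2491 regions were specific to DR+/+ and DR-/-. Without DR+/+ replicate 2 the numbers were 18486 and 1019, without DR-/- replicate 1 they were 6136 and 3623, and without DR-/- replicate 2 they were 7143 and 2907. In each of these settings DR+/+-specific regions were the more numerous. Leaving out a library changes the definitions, since its population then needs a peak in 1 list only and the other population absence from 1 list only. Without a DR+/+ library, regions private to 1 DR+/+ list count as DR+/+-specific, so those settings favour that class.

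**Figure D3:**
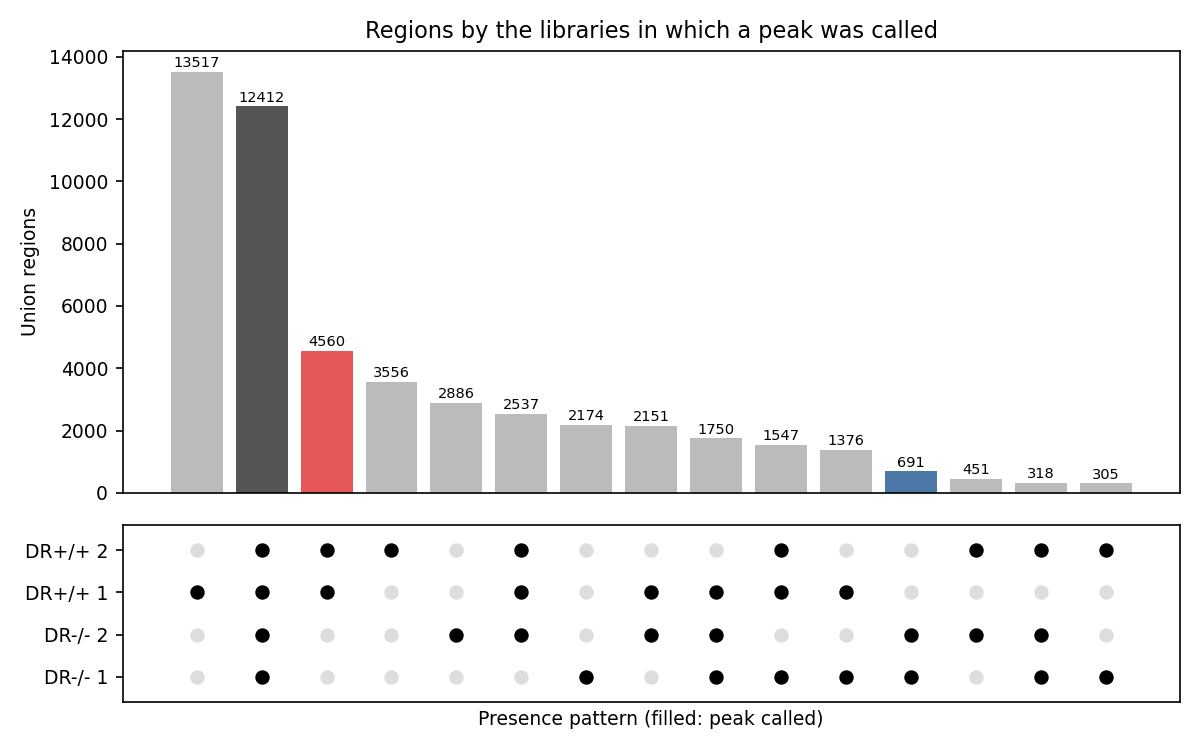
Number of union regions (y axis) for each combination of libraries in which a peak was called, shown by the filled dots under each bar. Red marks the 4560 DR+/+-specific regions, blue the 691 DR-/--specific regions and dark grey the 12412 regions called in all 4 libraries.

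Population-specific regions of both kinds were weaker and narrower than the regions common to all 4 libraries. Within the list of DR+/+ replicate 1, DR+/+-specific regions had a median q-value percentile of 45.2 (interquartile range 25.5 to 63.3), and within that of DR+/+ replicate 2 a median of 33.7 (17.1 to 53.4). Common regions had medians of 82.5 and 73.0 in these lists. DR-/--specific regions also ranked low in DR-/- replicates 1 and 2, with medians of 31.4 and 33.8 against 68.1 and 71.2 for common regions. Their medians were near that of DR+/+-specific regions in DR+/+ replicate 2 and below that in DR+/+ replicate 1. Weak peaks were found less often in every other list, so the lower ranks follow in large part from how these classes are defined. The peaks of DR+/+-specific regions were 183 and 159 bp wide in the median in DR+/+ replicates 1 and 2, and those of common regions 300 and 253 bp. As merged regions, DR+/+-specific and common regions measured 230 and 367 bp in the median, a difference of -137 bp (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest these can give). Merging over more libraries widens a region, which adds to this last difference. DR-/--specific regions were narrower still, with a median of 181 bp, 49 bp less than DR+/+-specific regions (p = 1e-05 in the same permutation test). Their peaks were 134 and 137 bp wide in the median in DR-/- replicates 1 and 2. The shortest peak was 108 and 115 bp in the DR+/+ lists and 104 and 103 bp in the DR-/- lists. Part of the difference between the populations may follow from these shortest widths.

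The strongest population-specific sites lay scattered over the genome. The 15 DR+/+-specific regions with the highest mean percentile were spread over 12 chromosomes or unplaced sequences, and their fold enrichment over local background, as the authors' files give it, ranged from 6.46 to 9.34 in replicate 1 and from 6.01 to 9.16 in replicate 2. The highest ranked lay on chromosome 1 at positions 60004961 to 60005207 of mm9, with 7.98-fold and 8.30-fold enrichment and 25 and 26 reads at the summit in DR+/+ replicates 1 and 2. The next lay on chromosome 6 at 147408612 to 147408784 (8.37-fold and 8.42-fold), chromosome 12 at 36277603 to 36277922 (8.57-fold and 7.67-fold) and chromosome 13 at 93866595 to 93867108 (7.13-fold and 7.93-fold). Chromosome 12 held 3 of the 15, the others being 59320200 to 59320355 and 21701919 to 21702240. A region on chromosome 17 at 89219456 to 89219979 was the widest, at 524 bp, and had 26 and 31 reads at its summit.

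The strongest DR-/--specific regions were shorter, between 109 and 259 bp. The first lay on chromosome 9 at 105974114 to 105974262, with 7.76-fold and 9.03-fold enrichment and 20 and 23 reads at the summit in DR-/- replicates 1 and 2. It was followed by regions on chromosome 4 at 88405666 to 88405789 (6.78-fold and 6.73-fold) and chromosome 3 at 97889790 to 97889960 (7.42-fold and 7.68-fold). The genes, exons or repeats at these positions were not analysed here, because no annotation of mm9 was used.

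Among the 33 chromosomes and unplaced sequences, an excess of DR+/+-specific regions was called on the X chromosome and on Y_random. On the X chromosome 231 of 1896 union regions were DR+/+-specific (12.2%, 95% Wilson interval 10.8 to 13.7%), compared with 9.08% over all chromosomes, an odds ratio of 1.41 (two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 33, adjusted p = 0.000131). On Y_random, sequence assigned to the Y chromosome without a position, 41 of 264 regions were DR+/+-specific (15.5%, 11.7 to 20.4%; odds ratio 1.85, adjusted p = 0.0126 in the same exact test). The 2 DR+/+ lists held 220 and 121 peaks on Y_random, and the 2 DR-/- lists 49 and 38. The treatment of multiply mapped reads is not given, so whether the Y_random regions are independent units of the test is not known. The X chromosome held 4.01% and 4.23% of the peaks of DR+/+ replicates 1 and 2 and 4.0% and 3.54% of those of DR-/- replicates 1 and 2, so DR+/+ replicate 1 and DR-/- replicate 1 hardly differed. The Y chromosome itself, with 6 of 27 regions DR+/+-specific, did not pass (adjusted p = 0.147 in the exact test), though it did without DR+/+ replicate 1, without DR+/+ replicate 2 and with common regions as background. Nor was an excess called on unplaced sequences with few regions, some of which had higher shares. Chromosome 11 had the opposite bias, with 198 of 2689 regions (7.36%, 6.44 to 8.41%; odds ratio 0.787, adjusted p = 0.0130 in the exact test). Chromosome 19 had a low share as well (6.97%), which did not pass the adjustment (adjusted p = 0.0758 in the exact test).

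DR-/--specific regions showed no such bias that could be called. None of the 33 chromosomes and unplaced sequences passed the adjusted threshold of 0.05 in Fisher's exact test. On the X chromosome 17 of 1896 regions were DR-/--specific (0.897%, 0.561 to 1.43%), compared with 1.38% overall. In a comparison chosen after the data were seen, 5.07% of DR+/+-specific and 2.46% of DR-/--specific regions lay on the X chromosome (Fisher's exact test, odds ratio 2.12, p = 0.00194, adjusted p = 0.0319 over all 33). For Y_random the shares were 0.899% and 0.289% (odds ratio 3.13, p = 0.113, adjusted p = 0.415 in the exact test), and for chromosome 11 they were 4.34% and 7.24% (odds ratio 0.582, adjusted p = 0.0319). Regions, not libraries, are the units of these tests, so their p-values describe these 4 lists.

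The X excess was not called with lists of equal length (odds ratio 1.36, adjusted p = 0.0657), without DR-/- replicate 2 (odds ratio 1.2, adjusted p = 0.0755) or with presence limited to the stronger 50% of each list (odds ratio 1.2, adjusted p = 1), all by the same exact test. It was called in the other 9 of 12 alternatives, and the odds ratio lay between 1.17 and 1.55 over all 12, with adjusted p from 3.25e-12 to 1 in the exact test. The excess on Y_random was called in 10 of the 12 alternatives, the exceptions being the 50% reciprocal overlap and the omission of DR-/- replicate 2. That omission also ended the call on chromosome 11. All of these alternatives start from the same peak lists, so they do not test how multiply mapped reads were treated.

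**Figure D4:**
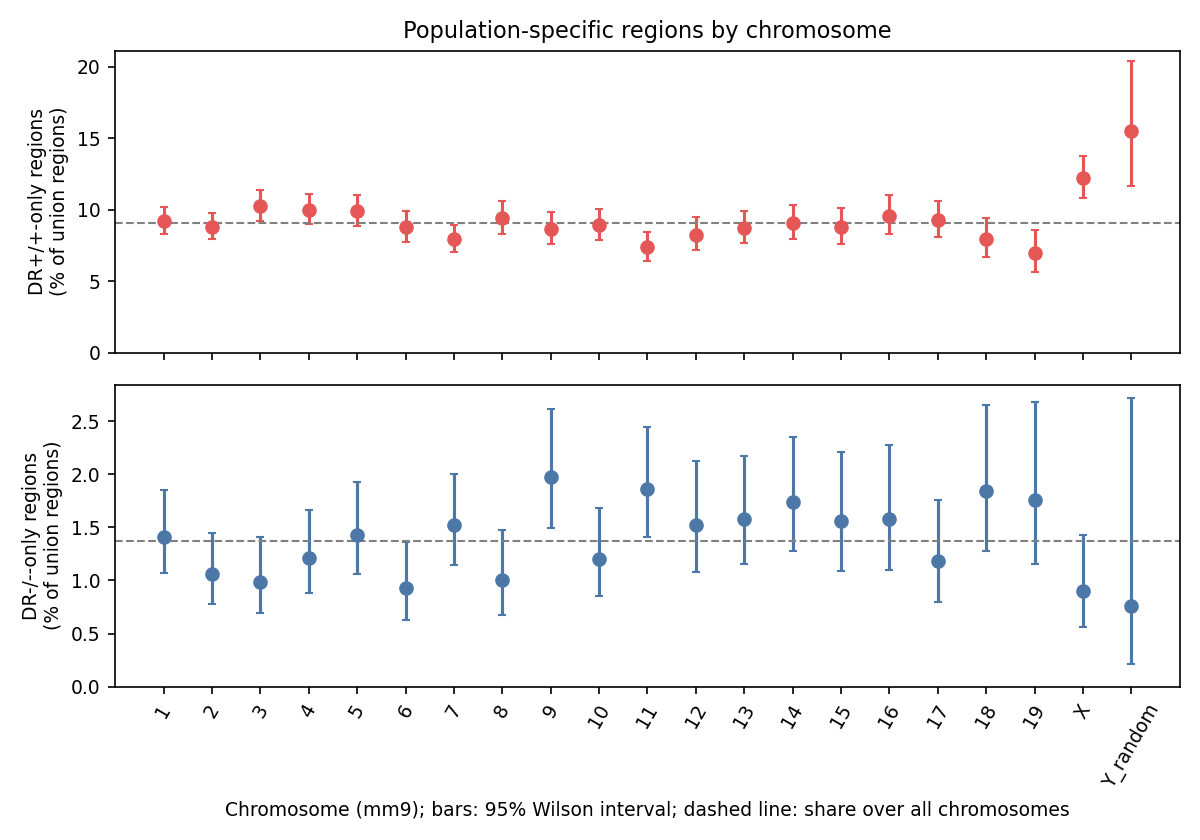
Share of union regions that were DR+/+-specific (top) or DR-/--specific (bottom), y axes in percent, for chromosomes 1 to 19, X and Y_random of mm9; the Y chromosome and other unplaced sequences are not drawn. Points are shares, bars 95% Wilson intervals and the dashed line the share over all chromosomes. The X chromosome (12.2%) and Y_random (15.5%) lie above the line of 9.08% in the top panel and chromosome 11 (7.36%) below it.

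Clusters of population-specific regions within chromosomes were sought in windows of 1 Mb holding at least 10 union regions. In 2190 windows, 0 passed the adjusted threshold for DR+/+-specific regions (one-sided Fisher's exact test with Benjamini-Hochberg adjustment), while 90 windows had an unadjusted p below 0.05. The window with the smallest p lay on the X chromosome at 9000001 to 10000000, where 8 of 16 regions were DR+/+-specific (adjusted p = 0.0662 in the exact test). Windows on chromosome 2 at 87000001 to 88000000 (7 of 16 regions) and chromosome 9 at 39000001 to 40000000 (6 of 12 regions) followed, each with an adjusted p of 0.232 in the exact test. Without DR-/- replicate 1 the X window was called (1 window), and 6 windows were called without DR+/+ replicate 2. For DR-/--specific regions 0 windows passed and 54 had an unadjusted p below 0.05. On simulated labels the test recovered 85.5% of windows with a planted 5-fold excess but only 18% of those with a 3-fold excess. The planted windows all held more union regions than the minimum of 10 and than the windows named here. Most clusters with a 3-fold excess would thus be missed even in such windows, and recovery in windows with fewer regions was not simulated.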

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

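The tests in this part were chosen after the results were seen, except the one that leaves out DR+/+ replicate 1. The 2 results concern the summit pileups, which the comparisons of presence do not use: the signal on the X chromosome relative to autosomes was higher in both DR+/+ libraries than in both DR-/- libraries. Over the 458 X and 11850 autosomal regions common to all 4 lists, the ratio of mean summit pileups was 0.859 in DR+/+ replicate 1 and 0.864 in DR+/+ replicate 2. It was 0.818 and 0.801 in DR-/- replicates 1 and 2. The means were 0.861 ± 0.00333 and 0.809 ± 0.0120 (SD, n = 2 each), and an exact permutation test gave p = 0.33, the smallest possible.

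This bears on the excess of DR+/+-specific regions on the X chromosome. The tables argue against the long list of DR+/+ replicate 1 as the only source of that excess. Without that list the X odds ratio was 1.35 (95% interval 1.21 to 1.52). A dependence on DR-/- replicate 2 stays open, since its X share of 3.54% was the lowest of all lists. The X odds ratio was 1.2 without DR-/- replicate 2 and 1.55 without DR-/- replicate 1. Whether a signal raised along the X as a whole explains the excess stays open as well. The lowest DR+/+ ratio of summit pileups exceeded the highest DR-/- ratio by a factor of 1.05. That factor is the observation itself, not a separate test of it. The group ratio was 1.06 (bootstrap over regions, 1.04 to 1.09), and part of it may not be particular to the X, because against the quartile of autosomal common regions with the fewest neighbours the factor was 1.03 (1.01 to 1.05). Whether that remainder reflects X dose, cell cycle stage or the population itself was not tested, and the bootstrap does not include the spread between libraries.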

How the results depend on the processing

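DR+/+-specific regions outnumbered DR-/--specific ones, and the difference in Jaccard index stayed above 0, under all alternatives run for them. The difference in peak number could not fall to 0 in its alternatives, since both DR+/+ lists were longer than both DR-/- lists. Nor could leaving out a library reverse the Jaccard difference, since both indices within populations exceeded all those between them. The counts depended on list length and on single libraries. The low number of reads per peak limits what absence from a list can show. With the top 50% of each list the difference in peak number was 5434, and 2309 regions were specific to DR+/+ and 347 to DR-/-. With lists of equal length these were 1791 and 1516, and 1 sequence (Y_random) had an excess of DR+/+-specific regions. Leaving out each library gave 3835 to 17902 for the difference in peak number, 0.0380 to 0.0929 for the difference in Jaccard index, 6136 to 18486 DR+/+-specific and 1019 to 3623 DR-/--specific regions, 0 to 4 chromosomes in excess and 0 to 6 windows. The 0 chromosomes came without DR-/- replicate 2, and 4 without DR+/+ replicate 1 and likewise without DR+/+ replicate 2 (3, X, Y and Y_random). The 6 windows came without DR+/+ replicate 2, and 1 without DR-/- replicate 1 (X at 9000001 to 10000000, adjusted p = 0.0449 in Fisher's exact test). These alternatives leave 1 library alone in its group. Windows of 500 kb, or with at least 5 regions, gave 0 calls. With 1 kb bins 2 windows were called, on chromosome 9 at 39000001 to 40000000 and chromosome 2 at 87000001 to 88000000. Among autosomes alone 0 chromosomes were in excess. Of the alternatives added after seeing the data, presence in the stronger 50% of the list gave 783 and 57 regions and 1 sequence in excess (Y_random), common regions as background gave 3 (X, Y and Y_random), and the replicate 2 libraries alone gave 10713 and 7904 regions and 4 chromosomes in excess (3, 14, X and Y_random). The stronger 50% for presence keeps the difference in list length, which favours DR+/+-specific regions. The cause of these changes was not tested, apart from the smaller number of peaks or libraries in the alternatives that drop some. The deficit on chromosome 11 was called in 9 of the 12 alternatives that include the X chromosome, and it was not called among autosomes alone. The replicate block gave the same 4560 and 691 regions and a mean within-pair difference of 10868.5 peaks, by construction, since a region present in both libraries of one population and neither of the other is so within each pair. Libraries sharing a replicate number across populations had a mean Jaccard index of 0.366, and those with different numbers 0.373. These means gave no sign of pairing by number. Each covers few pairs of lists of unequal length, so they cannot exclude it. The alternatives for promoters and gene lists and sequence content were not run.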

Other observations

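The tests in this part were chosen after the data were seen, except the comparison of ratios with lists of equal length and the comparison with random positions. DR+/+-specific regions lay farther from the regions common to all 4 lists than DR-/--specific regions did. Their median distance to the nearest common region was 77.7 kb (95% bootstrap interval 74.5 to 83 kb), compared with 45.2 kb (39.3 to 52.1 kb) for DR-/--specific regions. The difference of 32.4 kb had a permutation p of 1e-05 (adjusted p = 1e-05 over the 3 comparisons made on the full lists), the smallest that 100000 resamples can give. Regions, not libraries, are the units of these permutation tests and bootstrap intervals, so they describe these 4 lists. On autosomes alone the medians were 74.4 and 44.8 kb, and with lists of equal length 99.1 and 56.0 kb (permutation p = 1e-05 for each). Regions called in 1 library alone followed the populations in the same way, with medians of 66.5 and 65.7 kb for DR+/+ replicates 1 and 2 and 51.2 and 45.0 kb for DR-/- replicates 1 and 2.

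The strength of the shared sites moved in the same direction. Among common autosomal regions, the ratio of mean summit pileup between the quartile with the fewest common neighbours within 500 kb on either side (median 2) and the quartile with the most (median 13) was 0.891 and 0.882 in DR+/+ replicates 1 and 2. In DR-/- replicates 1 and 2 it was 0.838 and 0.839. An exact permutation test gave p = 0.33, the smallest possible with 2 against 2 libraries.

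For the distance pattern, technical explanations were tested. The long list of DR+/+ replicate 1 is argued against as its only cause, because regions private to DR+/+ replicate 2 lay 18.7 kb farther from common regions than regions private to 1 DR-/- library. That difference rests on 1 DR+/+ library and does not include the spread between libraries. Peaks placed at random by background reads are argued against, because 4560 regions were called in both DR+/+ lists and in neither DR-/- list, whereas 100 random shifts gave at most 165 shared peaks. Random positions also had a median distance of 102 kb, above the upper bound of 83 kb for DR+/+-specific regions (with lists of equal length 122 kb against an upper bound of 107 kb), although they include sequence where reads cannot be placed, and dropping the farthest 11.2% of them would remove that difference. Background that recurs at fixed positions in both libraries was not tested, and whether late-replicating or heterochromatic DNA was more accessible in the DR+/+ population is a hypothesis that these files leave untested.

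Whether the 6.60-fold excess of DR+/+-specific regions comes from list length stays open: the ratio was 1.18 (1.1 to 1.27) with lists of equal length, but equal lengths push it towards 1 whether the longer lists are technical or a real gain of sites. Deeper sequencing alone is argued against for DR+/+ replicate 1, whose peaks per unit of background were 1.49 times the mean of the other 3 libraries, and 1.49 times with the background divided by the shortest peak width. Its background of 1.66 was close to the 1.62 of DR+/+ replicate 2, which had 26866 peaks against 40933. For DR+/+ replicate 2 depth stays open: the same measure was 1.00 times the mean of the DR-/- libraries, but 1.11 times with the width taken into account, and the length to which reads were extended is not known. A broader set of accessible sites in the DR+/+ population and a library of higher enrichment in replicate 1 alone both remain open.

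A further hypothesis was that DR+/+-specific regions mark both long terminal repeats of full-length endogenous retroviruses such as MERVL, which would place them in pairs several kb apart. There were 22 pairs of DR+/+-specific regions 5 to 7 kb apart, within the 95% range of 16 to 36 pairs in 1000 random draws of as many union regions. No excess over these draws was seen. The draws came from all union regions, whereas DR+/+-specific regions lay farther from common regions, so the draws may hold too many pairs. They cannot show that such pairing is absent. Reads from near-identical repeat copies could also have been lost before peak calling, so the 22 pairs say nothing on MERVL copies as such. Pairs under 1 kb apart were more frequent than in random draws, with 91 observed and a 95% range of 43 to 73 in the draws.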
